A study of Homo sapiens with 8 samples.

How the data were processed

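ATAC-seq, which marks open chromatin by the insertion of adapters with a transposase, was applied to 8 libraries of the H1650 lung cancer line. The labels put them in 4 groups of 2 replicates: untreated, siControl, siMena11a and siMena. Transfected cells received siRNA at 20 nmol/L, per the labels' protocols.

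The deposited files are peak lists, 1 per library, so replicates were not pooled by the authors. The tools named in the submitters' processing notes were FastQC 0.11.5, Bowtie2 2.3.4.2, SAMtools 1.7 and MACS2 2.2.5, and the build was hg19. How reads were trimmed, filtered for duplicates or shifted for the transposase offset is not given in the sources used here. A row of a list is 1 summit, and a peak was taken as 1 distinct interval, so several summits of 1 interval counted as 1 peak. The score of a peak, deposited by the authors, is 10 times its −log10 q, rounded down, which held for at least 99.98% of the rows of each list. The fold of a peak is the authors' ratio of summit pileup to local background, with 1 added to each. The −log10 p and −log10 q of each peak are the authors' values from the peak caller, and the lowest −log10 q in each list lay just above 2.00, so the lists end at a q of 0.01. Scores and folds were used to describe, rank or filter peaks within 1 list, except that the stricter setting held all lists to the same score of 87. That score cuts the lists unequally, as their median −log10 q ran from 6.43 (siMena replicate 2) to 9.97 (siMena11a replicate 1). Folds were also set side by side between lists at regions listed in several of them, as a description of enrichment. The added 1 lowers such folds more in a library with fewer tags.

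The files give no read totals. From the deposited fold and −log10 p of a summit, its pileup in whole tags and its local background were recovered with the Poisson formula of the caller, within 0.001 of the deposited −log10 p for 100.0% of rows in all 8 lists. The floor shared by all local backgrounds of a list is the genome-wide background, the mean number of tags over a position after extension of tags to 200 bp. It scales with the total number of tags in a library and served as the measure of depth. The same recovery on 2000 simulated rows returned 100.0% of the simulated pileups.

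The peaks of all 8 lists were merged into regions wherever they overlapped or touched, and a region was open in a library if a peak overlapped it by at least 1 bp. For groups A and B, a region was gained if open in both A libraries and in neither B library, and lost in the opposite case. Comparisons were siMena11a against siControl, siMena against siControl, siControl against untreated, and siMena11a against siMena. A count has no test per region, since 2 libraries against 2 allow no exact p below 0.333. Each count was set beside the counts from the 2 other ways to divide the same 4 libraries. Group means of log2 peak number were compared by a two-sided exact permutation test. Similarity was the Jaccard index, the bp shared by 2 lists over the bp in either, after shortening every list to the 1020 peaks with the highest −log10 q. Its mean over same-group pairs was tested by a one-sided exact permutation over the 105 divisions of 8 libraries into pairs, and over same-numbered pairs by the 35 divisions into 2 sets of 4. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error over regions only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

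The code for region calls was checked on simulated data. In each of the 4 comparisons, 400 regions open in all 4 libraries were closed by simulation in 1 of the groups. All 400 were called, over 46665 regions, which follows from the definition of a call and checks the code only. A second simulation closed 200 regions open in replicate 1 of a group in both libraries of the other group. For siMena11a against siControl it called 8.00% of the gained and 15.5% of the lost regions, and for siMena against siControl 5.00% and 17.5%. For siControl against untreated the shares were 18.0% and 51.5%, and for siMena11a against siMena 3.50% and 6.50%. The rest were missed because replicate 2 did not list them.

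The regions named were fixed by rule before the data were examined: in each comparison, the 5 gained and 5 lost regions whose lowest score percentile within the lists that carry them was highest. Coordinates are hg19, counted from 1. No annotation or sequence of hg19 was used here, so genes near regions, the ENAH promoter, promoter shares, motifs and the 16 gene lists fixed beforehand (among them interferon, antigen presentation, actin and epithelial genes) were not analysed here. Small interfering RNA acts on mRNA, so accessibility at ENAH would not check the knockdown. Alternatives were shortened lists, a stricter score threshold of 87, the median over all peaks, another overlap rule, bins of 500 bp, bp in place of peak number, chromosomes 1 to 22 and X alone, the replicate number as a block, and leaving out each library. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.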

Results

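Open chromatin was mapped by ATAC-seq in H1650, a human non-small cell lung cancer line, after silencing of hMENA. This actin regulatory protein is encoded by ENAH, and hMENA11a is its epithelial isoform. Untreated cells were compared with cells transfected with a non-targeting siRNA pool (siControl), with siRNAs matching exon 11a (siMena11a), or with a pool against hMENA as a whole (siMena), with 2 libraries per group. The merged peaks of the 8 libraries made 46665 regions covering 21.9 Mb, with a median width of 394 bp. Of these regions, 14570 (31.2%) were open in 1 library only and 542 (1.16%) in all 8. Regions open in 1 library had a median width of 235 bp, and those open in all 8 of 939 bp. A region is the union of its peaks, so its width grows with the libraries that list it, also in the widths given below.

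Replicate 1 of the untreated, siControl, siMena11a and siMena groups listed 34782, 27304, 35472 and 14678 peaks. Replicate 2 listed 22424, 5231, 2832 and 1020. The genome-wide background, in tags per position, was 0.538, 0.935, 0.881 and 0.725 in the replicate 1 libraries and 1.09, 2.27, 2.54 and 2.88 in the replicate 2 libraries, so the shortest lists came from the libraries with the most tags. At the 501 regions on assembled chromosomes open in all 8 libraries, the median fold over local background was 11.7, 10.7, 10.8 and 9.21 in replicate 1 and 10.1, 6.78, 5.64 and 4.59 in replicate 2. The short lists were largely contained in the long ones. Of the 5072 regions of siControl replicate 2, 90.8% were also open in siControl replicate 1, and of the 14110 regions of siMena replicate 1, 94.0% were open in siControl replicate 1 and 96.5% in siMena11a replicate 1. Of the 997 regions of siMena replicate 2, 69.0% were open in siMena replicate 1 and 84.8% in siControl replicate 2.

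**Figure D1:**
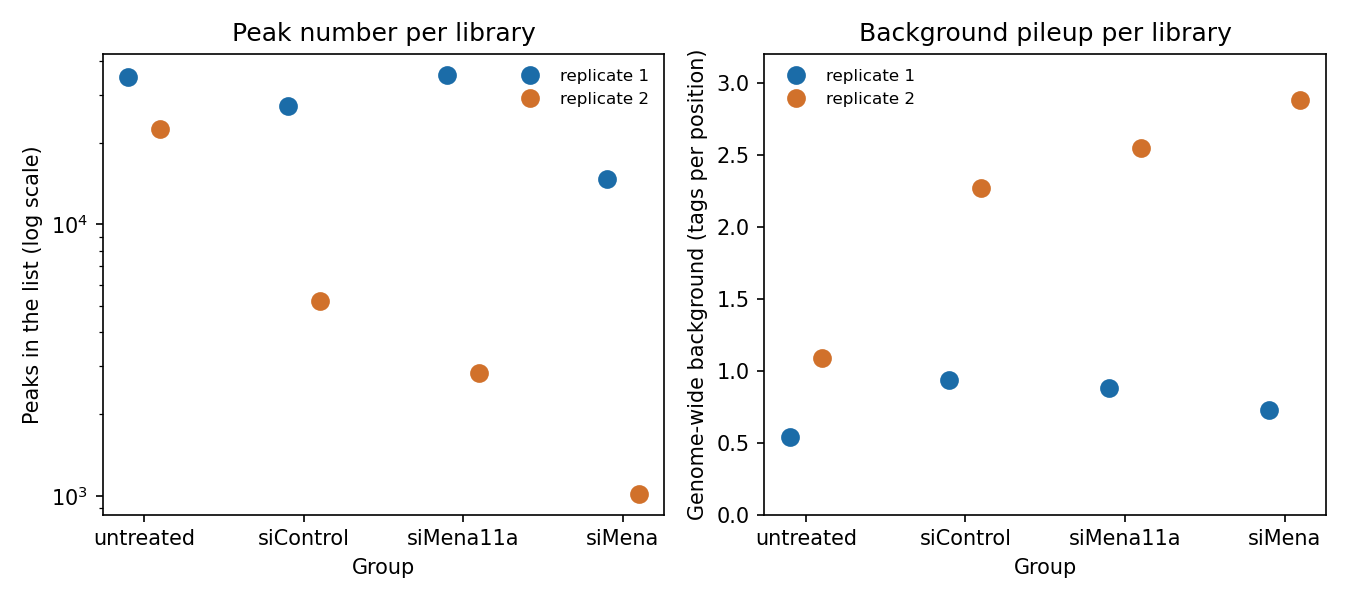
Number of listed peaks (left, log scale) and genome-wide background in tags per position (right) for each library, by group; blue points are replicate 1 and orange points replicate 2. The 3 transfected replicate 2 libraries have the fewest peaks, 5231, 2832 and 1020, and the highest backgrounds, 2.27, 2.54 and 2.88.

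The index of overlap was higher on average between libraries of the same replicate number than between libraries of the same group, with exceptions. With every list shortened to its 1020 strongest peaks, the Jaccard index was 0.354 between the untreated replicates, 0.273 between the siControl, 0.178 between the siMena11a and 0.146 between the siMena replicates. Their mean of 0.237 lay below the mean of 0.278 over all pairs (one-sided exact permutation p = 0.695 over all divisions of the libraries into pairs). Among the pairings of a replicate 1 with a replicate 2 library alone it lay above their mean of 0.230 (p = 0.125, one-sided exact permutation with the replicate number as a block). Pairs with the same replicate number had a mean index of 0.342, the highest of the 35 divisions of the 8 libraries into sets of 4 (one-sided exact permutation p = 0.0286, the smallest that 35 divisions can give). The replicate 1 libraries had indices from 0.363 (siMena11a with siMena) to 0.449 (untreated with siControl). Among replicate 2 libraries, siControl with siMena11a reached 0.405 and untreated with siMena 0.120. Untreated replicate 2 was closer to each replicate 1 library (0.320 to 0.366) than to any other replicate 2 library (0.120 to 0.281), and siControl replicate 2 closer to siMena replicate 1 (0.284) than to siMena replicate 2 (0.275). Without untreated, siControl, siMena11a or siMena replicate 1, the p by replicate number was 0.0571, 0.0571, 0.0857 and 0.0571, and with full lists 0.0571. The region counts are therefore also given within each replicate number.

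**Figure D2:**
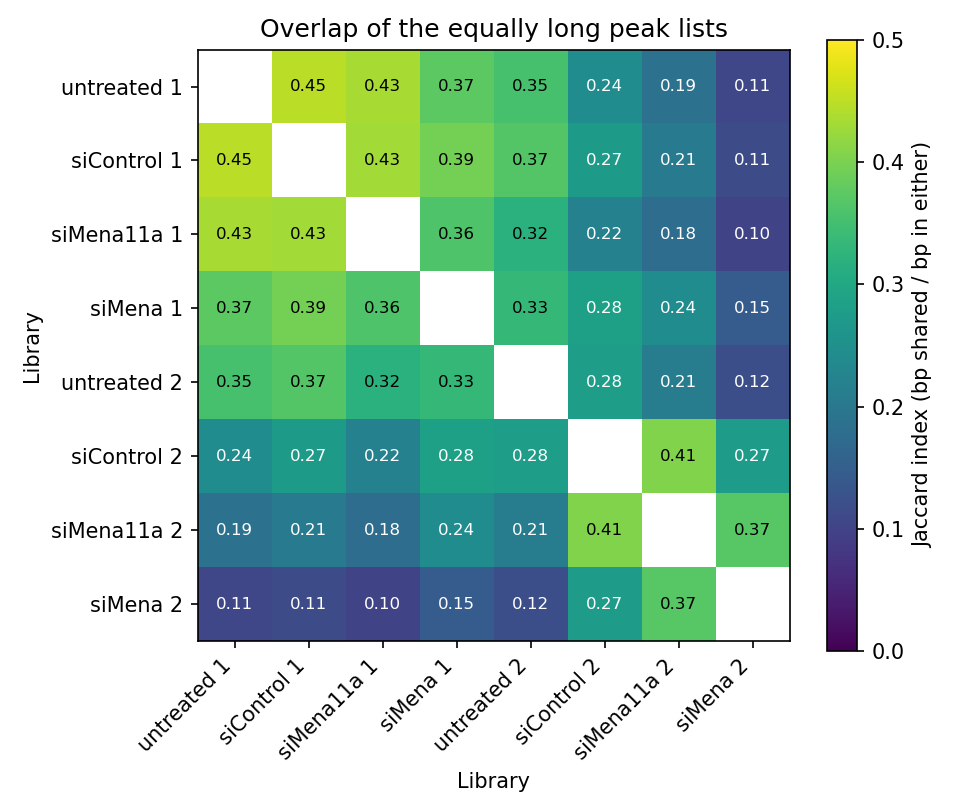
Jaccard index (bp shared over bp in either list) between the 8 libraries, each list shortened to 1020 peaks; rows and columns are libraries, ordered by replicate number. Replicate 1 libraries form a block with indices from 0.363 to 0.449, and same-group pairs lie between 0.146 and 0.354.

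Silencing of the 11a isoform was compared with the non-targeting siRNA to ask which regions open or close with it. Both siMena11a libraries listed, and neither siControl library did, 13 regions, against 26 regions with the opposite pattern and 2065 open in all 4 libraries. The gained region with the highest score percentile lay on chromosome 7 from 12106234 to 12106611, with a fold of 8.80 in siMena11a replicate 1 and 4.30 in replicate 2 and with authors' scores of 228 and 62. The others named lay on chromosome 3 (159590184 to 159590563), chromosome 8 (134587615 to 134588057), chromosome 2 (14775455 to 14775899) and the unplaced contig Un_gl000216 (158700 to 159013). Among the lost regions, the first was on chromosome 4 from 67044614 to 67045191, with a fold of 10.0 in siControl replicate 1 and 5.82 in replicate 2 and scores of 159 and 75. It was followed by regions on chromosome 9 (2655336 to 2655983), chromosome 5 (146783619 to 146784237), chromosome 4 (145277533 to 145277838) and the same contig (23385 to 23652). Of the 13 gained regions, 9 were also open in untreated replicate 1 and 7 in untreated replicate 2, and of the 26 lost regions 13 were open in each untreated library. Lost regions had a median width of 376.5 bp and a median fold of 5.03 in siControl replicate 1, against 869 bp and 9.93 for the 2065 shared regions. The gained and lost regions of the treatment were fewer than those of the split by replicate number, where 18661 regions were open in both replicate 1 libraries only and 144 in both replicate 2 libraries only. The crossed split gave 75 regions open only in siMena11a replicate 1 and siControl replicate 2 and 7 only in the other two libraries. Within replicate 1, siMena11a had 11295 regions that siControl lacked and siControl 2916 that siMena11a lacked, and within replicate 2 these were 479 and 2787, so the direction differed between the replicates. Leaving out siMena11a replicate 1, siMena11a replicate 2, siControl replicate 1 or siControl replicate 2 gave 137, 11188, 348 or 45 gained and 2495, 70, 243 or 2865 lost regions. None of the named regions was called when the 4 lists were shortened to the same length, where 92 regions were gained and 160 lost, or held to the stricter score, where 1 was gained and 9 were lost. A named call could fail there only where a list carrying the region lost its peak. With peaks required to cover 50% of a region, the gained region on chromosome 8 was not called. Nor were the lost regions on chromosome 9, on chromosome 5 and, from 67044614, on chromosome 4.

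Silencing of hMENA as a whole was compared with the same control for the same question. In this comparison 1 region was gained, 481 were lost and 636 were open in all 4 libraries. The gained region, on the contig 9_gl000199_random from 108090 to 108378, had folds of 2.58 and 2.24 and was also open in untreated replicate 2 and siMena11a replicate 2. The lost region with the highest score percentile lay on chromosome 8 from 118400520 to 118401079, with a fold of 11.0 in siControl replicate 1 and 6.56 in replicate 2 and scores of 246 and 140. It was open in all 6 libraries outside the siMena group. A region on chromosome 1 (107619398 to 107619850) had folds of 11.4 and 10.4 and scores of 207 and 227. The other lost regions named were on chromosome 8 (116990358 to 116990975), chromosome 7 (16524349 to 16524816) and chromosome 5 (136570627 to 136571430), each open in both untreated libraries and in siMena11a replicate 1. Of the 481 lost regions, 449 (93.3%) were open in untreated replicate 1, 432 (89.8%) in untreated replicate 2, 460 (95.6%) in siMena11a replicate 1 and 60 (12.5%) in siMena11a replicate 2. Chromosomes 2, 3 and 4 held the most of them, 58, 48 and 47 regions. The same chromosomes held 11.4%, 8.26% and 6.46% of the peaks of siControl replicate 2, a list that every lost region must be in. A preference for chromosomes was not tested. Their median width was 545 bp and their median fold in siControl replicate 1 was 6.63, against 915 bp and 10.1 for the 636 shared regions. The split by replicate number gave 9177 and 124 regions, and the crossed split 7 with siMena replicate 1 and siControl replicate 2 and 10 with the other 2 libraries. Both siMena lists were shorter than the siControl list of the same number, with 0.538 and 0.195 times the peaks. The list lengths alone favour lost regions over gained ones and over the crossed split, so these counts do not separate treatment from list length. Within replicate 1, siMena lacked 13180 regions of siControl and had 844 that siControl lacked, and within replicate 2 these were 4227 and 152. Without siMena replicate 1, siMena replicate 2, siControl replicate 1 or siControl replicate 2, the gained regions numbered 119, 809, 24 or 29. In the same order, the lost regions numbered 3911, 538, 790 or 13113. None of the named regions was called in lists shortened to the same length, where 34 regions were gained and 81 lost, and the gained region was also not called under the stricter score, which left 0 gained and 257 lost regions. With peaks required to cover 50% of a region, the lost regions from 118400520 on chromosome 8 and from 136570627 on chromosome 5 were not called.

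The effect of transfection itself was examined by setting siControl against untreated cells. Here 56 regions were gained, 1702 were lost and 4356 were open in all 4 libraries. The first gained region, on chromosome 8 from 144940230 to 144940818, had a fold of 5.98 in siControl replicate 1 and 4.93 in replicate 2 and scores of 139 and 216. Together with a region on chromosome 8 from 142502299 to 142502807, with folds of 4.97 and 4.39, it was open in all 6 transfected libraries and in neither untreated library. A separate region close to the latter, from 142503020 to 142503343, was open in both untreated libraries, with folds of 7.32 and 5.39. The regions from 144940230 and from 142502299 kept at least 0.8 of their replicate 1 fold in replicate 2 of each transfected group. Only 49 (9.25%) of 530 regions on chromosomes 1 to 22 and X open in all 6 transfected libraries did so. Listing in these replicate 2 libraries needed a fold of at least 3.61 to 3.67 at the genome-wide background. Regions with a low replicate 1 fold could thus enter the 530 mainly with a high ratio, so the 9.25% does not set these regions apart. The other gained regions named were on chromosome 12 (1683434 to 1683733), chromosome 1 (148853604 to 148854122) and chromosome 8 (86747455 to 86748230). Of the 56 gained regions, 41 (73.2%) were open in siMena11a replicate 2 and 39 (69.6%) in siMena replicate 2. Only 18 (32.1%) were open in siMena11a replicate 1 and 13 (23.2%) in siMena replicate 1, although these lists are longer. Contigs outside the assembled chromosomes held 9 of the 56. The first lost region was on chromosome 3 from 134039555 to 134039942, with a fold of 10.2 in untreated replicate 1 and 7.87 in replicate 2 and scores of 193 and 170. Regions on chromosome 14 (60714692 to 60714959), chromosome 5 (110725086 to 110725438), chromosome 6 (10237896 to 10238232) and chromosome X (115363866 to 115364569) followed, with scores from 153 to 177 in the untreated lists. All 5 named lost regions were open in siMena11a replicate 1, a transfected library. Of the 1702 lost regions, 1246 (73.2%) were open there, 136 (7.99%) in siMena replicate 1, 5 in siMena11a replicate 2 and 1 in siMena replicate 2. The split by replicate number gave 7495 and 82 regions, and the crossed split 570 with siControl replicate 1 and untreated replicate 2 and 23 with the other 2 libraries. Both siControl lists were shorter than the untreated list of the same number, with 0.785 and 0.233 times the peaks, which alone favours lost regions. Within replicate 1, siControl had 3234 regions that untreated lacked and lacked 10592, and within replicate 2 these were 498 and 17086. Without siControl replicate 1, siControl replicate 2, untreated replicate 1 or untreated replicate 2, 359, 2588, 172 or 132 regions were gained. In the same order, 12947, 1762, 5271 or 10509 were lost. In lists shortened to the same length, 218 regions were gained and 216 lost, and none of the named regions was among them. The region on chromosome 8 from 86747455 to 86748230 was also not called under the stricter score, which left 19 gained and 930 lost regions. The lost region on chromosome X was not called with peaks required to cover 50% of a region.

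The isoform-specific and the overall knockdown were compared to ask whether they differ. Relative to siMena, siMena11a had 112 gained and 3 lost regions, and 597 regions were open in all 4 libraries. The gained region on chromosome 1 from 49344117 to 49344652 had a fold of 10.0 in siMena11a replicate 1 and 6.77 in replicate 2 and scores of 181 and 109. It was followed by regions on chromosome 2 (33294871 to 33295672), chromosome 7 (40756837 to 40757216), chromosome 6 (161459131 to 161459909) and chromosome 8 (118400520 to 118401079), the last of which also led the regions lost with siMena against siControl. The 3 lost regions lay on chromosome 7 (157943985 to 157944246), chromosome 20 (59904292 to 59904554) and chromosome 4 (9270068 to 9270372), and each was also open in siControl replicate 2. Of the 112 gained regions, 102 (91.1%) were open in untreated replicate 1, 94 (83.9%) in siControl replicate 1 and 65 (58.0%) in siControl replicate 2. Both siMena lists were shorter than the siMena11a list of the same number, by 2.42-fold in replicate 1 and 2.78-fold in replicate 2. The split by replicate number gave 11270 and 137 regions, and the crossed split 12 with siMena11a replicate 1 and siMena replicate 2 and 8 with the other two libraries. Within replicate 1, siMena11a had 21215 regions that siMena lacked and lacked 500, and within replicate 2 these were 1949 and 182. Without siMena11a replicate 1, siMena11a replicate 2, siMena replicate 1 or siMena replicate 2, 251, 21157, 1802 or 158 regions were gained. In the same order, 56, 38, 117 or 457 were lost. None of the named regions was called in lists shortened to the same length, where 50 regions were gained and 27 lost, and the 3 lost regions were not called under the stricter score, which left 30 gained and 0 lost. Of the gained regions named, only that on chromosome 7 was called with peaks required to cover 50% of a region.

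No difference in peak number between groups passed a test. Mean peak numbers were 28603 ± 8738 (SD, n = 2) in untreated, 16268 ± 15608 in siControl, 19152 ± 23080 in siMena11a and 7849 ± 9658 in siMena libraries. The difference of mean log2 peak number was -0.25 for siMena11a minus siControl (two-sided exact permutation p = 1.0), opposite in sign to the difference of the mean peak numbers, -1.63 for siMena minus siControl (p = 0.667), -1.22 for siControl minus untreated (p = 0.667) and 1.37 for siMena11a minus siMena (p = 0.667). With 2 libraries against 2, no p can fall below 0.05. The first difference turned positive without siMena11a replicate 2 (1.57) or siControl replicate 1 (0.94), and the siMena minus siControl difference without siMena replicate 2 (0.30). The siControl minus untreated difference was -0.03 without siControl replicate 2 and -2.42 without siControl replicate 1. The siMena11a minus siMena difference turned negative without siMena11a replicate 1 (-0.45) or siMena replicate 2 (-0.55).

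Regions of the long lists were found in the other libraries to different extents on different chromosomes. Untreated, siControl and siMena11a replicate 1 shared 21800 regions. Of these, siControl replicate 2 listed 20.4% (95% interval 19.9 to 21.0), siMena11a replicate 2 listed 10.7% (10.3 to 11.1) and siMena replicate 2 listed 2.84% (2.62 to 3.07). Untreated replicate 2 listed 70.3% and siMena replicate 1 listed 59.1%. On chromosome 4 siControl replicate 2 listed 28.5% of 1000 regions (25.7 to 31.4), on chromosome 17 8.37% of 741 (6.47 to 10.6), on chromosome 19 3.97% of 831 (2.75 to 5.53) and on chromosome 22 2.39% of 335 (1.04 to 4.65). Chromosomes 13 and X had 13.8% and 13.5% in siControl replicate 2, and 4.71% and 4.01% in siMena11a replicate 2, and chromosome X had 0.382% in siMena replicate 2. siMena replicate 1 listed 60.2% on chromosome 4, 53.7% on chromosome 17, 62.0% on chromosome 19 and 48.1% on chromosome 22.

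**Figure D3:**
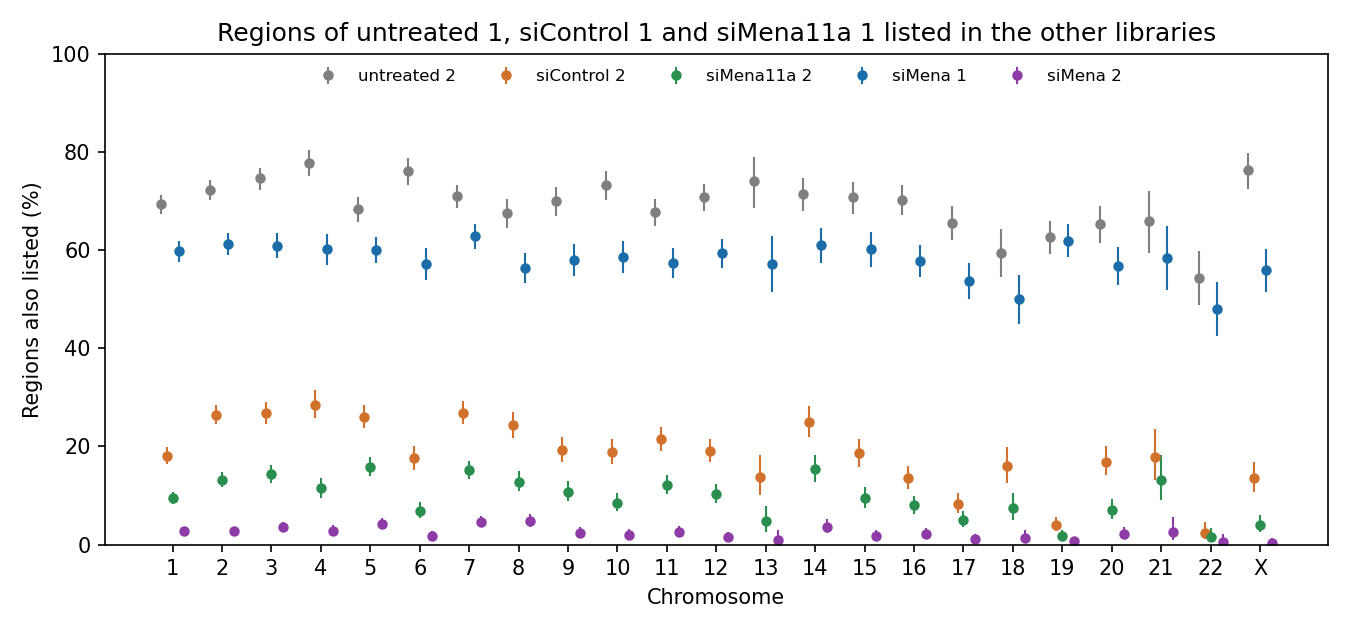
Percent of the regions shared by untreated, siControl and siMena11a replicate 1 that the other 5 libraries also listed, by chromosome; points are libraries and bars are 95% exact binomial intervals. In siControl replicate 2 the percentage is 28.5 on chromosome 4 and 3.97 on chromosome 19, while siMena replicate 1 has 60.2 and 62.0.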

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

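Nearly every region count moved by over 1.5 times with the list length, the threshold or the libraries used, and no comparison between groups passed a test. The stricter overlap rule, the read-file split and the use of replicate 1 alone for peak number were chosen after seeing the data; all other alternatives were fixed before the data were examined. The planned rule of 50% overlap of region or peak changed nothing by construction, since a merged region holds its peaks whole. Counts are given as gained and lost, in the order siMena11a against siControl, siMena against siControl, siControl against untreated, and siMena11a against siMena.

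Lists shortened to the shortest of the 4 gave 92 and 160, 34 and 81, 218 and 216, and 50 and 27. The stricter score gave 1 and 9, 0 and 257, 19 and 930, and 30 and 0. Bins of 500 bp gave 49 and 106, 6 and 736, 124 gained, and 235 and 7. On chromosomes 1 to 22 and X alone no region was gained (0) for siMena against siControl, and with peaks required to cover 50% of a region 4 were. The cause was not tested beyond the construction of these settings. Of the 34 named calls, 0 held in shortened lists, 19 under the stricter score and 23 with the 50% cover. The region on chromosome 8 from 118400520 to 118401079 counts both for siMena against siControl and for siMena11a against siMena. These settings only remove peaks, so a named call could fail only where a list carrying the region lost its peak. They cannot tell whether its absence from the other group came from a short list.

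The labels name no batch or culture shared by libraries of 1 number, and with 2 pairs the data cannot establish pairing. With the replicate block, replicate 1 alone gave 11295 and 2916, 844 and 13180, 3234 and 10592, and 21215 and 500 regions, and replicate 2 alone 479 and 2787, 152 and 4227, 498 and 17086, and 1949 and 182. Within replicate numbers the mean differences of log2 peak number stayed at -0.25, -1.63, -1.22 and 1.37 by construction, and no sign-flip p can fall below 0.5. Over the 24 pairings of a replicate 1 with a replicate 2 library, the same-group mean index of 0.237 lay above the mean pairing of 0.230 (one-sided exact permutation p = 0.125), where without the block it lay below.

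Leaving out 1 library at a time, gained counts ranged from 45 to 11188, 24 to 809, 132 to 2588, and 158 to 21157, and lost counts from 70 to 2865, 538 to 13113, 1762 to 12947, and 38 to 457. Differences of log2 peak number ranged from -2.08 to 1.57, -3.55 to 0.30, -2.42 to -0.03, and -0.55 to 3.30. With replicate 1 libraries only, the difference for siMena11a minus siControl was 0.38. The same-number mean index ranged from 0.315 to 0.388 (exact permutation p from 0.0286 to 0.0857); with full lists it was 0.316 (p = 0.0571), and a split by read-file suffix gave 0.306 (p = 0.0893, 56 divisions). Similarity by group stayed at p from 0.514 to 0.924 in all unblocked settings. The alternatives for gene lists, nearest genes and motifs were not run, as no hg19 annotation or sequence was used. The shortest lists came from the libraries with the most tags, so a low total number of tags did not set their length. That total does not measure the depth around the peaks.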

Other observations

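Among the tests of explanations given here, the scaling of siControl replicate 1 pileups to the depth of siMena replicate 1 was set before its result was seen, and all others, including their present bounds, were chosen after.

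Peaks on contigs outside the assembled chromosomes were almost equally many in every list, from 91 in siMena replicate 1 to 134 in siMena11a replicate 1, so that they made up 0.308% of the peaks of untreated replicate 1 and 12.6% of those of siMena replicate 2. Most regions had a lower fold in the transfected replicate 2 libraries than in replicate 1 of the same group: over the 530 regions on chromosomes 1 to 22 and X open in all 6 transfected libraries, the median ratio of replicate 2 over replicate 1 was 0.569. In 49 of them (9.25%) the ratio was at least 0.8 in all 3 groups, as in 28 of 52 regions on other contigs. A region had to be listed in replicate 2 to be counted, so a low replicate 1 fold favoured a high ratio. These 49 regions, singled out after their values were seen, included neighbouring ones on chromosome 2 (87641696 to 87642239 and 87644121 to 87644631) and regions near chromosome starts, such as chromosome 5 from 10039 to 11804, with a fold of 5.70 and 5.29 in the siControl libraries, and chromosome 17 from 51205 to 51725, with 4.93 and 6.76.

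Only 4 regions were open in all 6 transfected libraries and in neither untreated library. They lay on chromosome 8 (142502299 to 142502807 and 144940230 to 144940818), chromosome 1 (236877019 to 236877873) and chromosome 17 (21902680 to 21903387). The first of them lay close to a region from 142503020 to 142503343 that was open in both untreated libraries, with folds of 7.32 and 5.39. Of the 4 regions, all but that on chromosome 1 were among the 49 regions above, whose fold ratio was at least 0.8 in all 3 groups. For the region on chromosome 8 from 144940230 to 144940818, the fold was 5.98, 4.93, 5.30, 5.39, 5.58 and 5.35 in siControl, siMena11a and siMena replicates 1 and 2. By the same count, 57 regions were open everywhere except in the siMena pair, 0 everywhere except in the siControl or the siMena11a pair, and 1950 everywhere except in siMena11a and siMena replicate 2. The siMena list was the shortest of each replicate number, which alone favours that pair as the missing one.

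Local background around summits, relative to the genome-wide one, had its highest chromosome median on chromosome 20 in all 8 libraries (from 2.52 to 3.36) and low medians on chromosome 13 (1.00 to 1.67) and chromosome X (1.00 to 1.75). The 472 windows of 5 Mb, with a median of 2.22, were ranked by their lowest value among the 5 libraries with at least 10000 peaks. Window ends were not clipped at chromosome ends, so the last window of a chromosome can hold less than 5 Mb. The first lay on chromosome 8 from 145000001 to 150000000 (4.23 to 6.56), on chromosome 5 from 1 to 5000000 (3.69 to 5.27) and on chromosome 20 from 60000001 to 65000000 (3.67 to 5.22). Further down this ranking, chromosome 20 from 25000001 to 30000000 had a higher top value (3.51 to 5.54) than the last 2 of these. Also high was chromosome 8 from 140000001 to 145000000 (3.60 to 5.24). That window holds both chromosome 8 regions open in all 6 transfected libraries and in neither untreated library.

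The siControl, siMena11a and siMena replicate 2 lists were short. A lower total number of tags is argued against, since their genome-wide background was at least 2.42 times that of replicate 1 of the same group. That total counts tags wherever they lie, so fewer tags around the peaks are not excluded by it. Tags lying elsewhere that inflate the total are argued against as the whole cause, because at the regions open in all 8 libraries the pileup relative to the local background was lower in replicate 2, by a quotient of 0.629 or less in each transfected group, but such tags stay open as a part of it, since the local background at the 488, 470 and 425 of these regions where it exceeded the genome-wide one was 0.928, 0.784 and 1.46 times that of replicate 1 in siControl, siMena11a and siMena, while the genome-wide one was 2.42, 2.89 and 3.97 times. At narrow regions with no other within 5 kb the local background, which cannot lie below the genome-wide one, was 2.60 against 1.7 tags, 3.00 against 1.90 and 3.96 against 1.4 in the same groups, so its size depends on the regions taken. Knockdown of hMENA is argued against as a cause common to the 3 lists, as siControl replicate 2 had 0.192 times the peaks of siControl replicate 1. Lower enrichment over background remains a candidate explanation, with the highest of the 3 median folds at shared regions 6.78 and the lowest of the other 5 libraries 9.21.

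In the same 3 libraries, regions on chromosomes 17, 19 and 22, chosen after their low values were seen, were listed less often than others, 5.4% against 21.7% in siControl, 2.99% against 11.3% in siMena11a and 0.839% against 2.81% in siMena replicate 2, but they were not the only low ones: chromosome X had the lowest share in siMena replicate 2 (0.382%), and X (4.01%) and chromosome 13 (4.71%) lay below chromosome 17 (4.99%) in siMena11a replicate 2. Weaker peaks there are argued against in 2 libraries: at equal strength in the replicate 1 lists the ratio was 0.3327 (95% bootstrap interval over regions 0.272 to 0.388) in siControl and 0.415 (0.315 to 0.517) in siMena11a replicate 2, while 0.530 (0.274 to 0.806) in siMena replicate 2 leaves it open, and a first bound, set before the result was seen and asking for a ratio under 0.5 in all 3 libraries, had left all of them undecided. The ratio was 0.932 in untreated replicate 2 and 1.05 in siMena replicate 1. A higher local background, which makes a peak harder to list, is argued against as far as siControl replicate 1 shows it, since at equal strength and equal local background in that library the ratio was 0.325 (0.272 to 0.386) in siControl, 0.399 (0.307 to 0.494) in siMena11a and 0.492 (0.258 to 0.758) in siMena replicate 2. The background of the replicate 2 libraries at regions they did not list is unknown, so a background particular to them stays open. At summits they did list, the median relative background on these chromosomes against elsewhere goes with it. It was 1.787 against 1.439 in siControl, 1.871 against 1.439 in siMena11a and 2.336 against 1.55 in siMena replicate 2. In siControl replicate 1 it was 2.459 against 2.246. A bias by GC content may remain and was not tested, for want of a sequence, and no biological explanation was tested.

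siMena replicate 1 listed 50.9% of the siControl replicate 1 peaks. Lower total depth is argued against: with pileups scaled to its depth, 97.1% would have passed, and untreated replicate 1, with fewer tags, listed 88.1%. The gap of 46.2 percentage points compares with 10.4 from siControl to siMena11a and 5.72 from siControl to untreated replicate 1 under the same scaling, which ignores sampling noise, but without knockdown untreated replicate 2 also listed only 52.1% of the untreated replicate 1 peaks and siControl replicate 1 69.4%. Knockdown of hMENA cannot be told apart from library quality or batch, because the median fold at shared regions differed by -1.84 on average (-1.49 in replicate 1 and -2.19 in replicate 2) while libraries of 1 group differed by up to 5.18. The 1 added to pileup and background may account for part of the replicate 1 difference, since siMena had 0.7755 times the background of siControl there. In replicate 2 siMena had the higher background. The read-file names kept in the lists carry the same suffix in siMena replicate 1 as in all 4 replicate 2 libraries and not in the other replicate 1 libraries. In shortened lists the overlap index of siMena replicate 1 was higher with each replicate 1 library (0.363 to 0.395) than with any replicate 2 library (0.146 to 0.334). In full lists its index with untreated replicate 2 (0.3845) was above those with untreated (0.3373) and siMena11a replicate 1 (0.3143). It was below that with siControl replicate 1 (0.4045), and the other replicate 2 libraries were lower (0.0399 to 0.2329). A shared batch was not tested further.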
